A study of Mus musculus with 6 samples.

How the data were processed

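MIN6 cells were electroporated with a control siRNA or an siRNA against TDP-43, per the labels' protocols. Total RNA was labelled as biotinylated cRNA with a 3' in vitro transcription kit and hybridised to Affymetrix mouse arrays, 3 per group. The authors processed the arrays with MAS5, per the submitters' processing notes, with no version given in the sources used here. The deposited table holds the signal intensity on a linear scale for 45101 probe sets and 6 arrays. As checked on the table, the mean of each array without the highest and lowest 2% of values was 500.003 and the lowest value was 1. Such equal means fit a scaling of every array to a target of about 500. Detection calls were not used here.

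Probe sets were named from the platform annotation: 34945 had 1 gene, 932 several and 9160 were not listed with a gene, beside 64 control probe sets. Symbols were brought up to date through Entrez gene numbers with a RefSeq gene table of the mouse assembly GRCm38.p6 (34741 matched), which also gave gene spans for 12554 of the genes tested. No position in the genome is reported.

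The value 12 was added to each signal (the 20th percentile of the table, rounded) before log2, with no further scaling. The 40% of probe sets with the lowest mean over the 6 arrays were left out, as were control probe sets. Of the 27022 that remained, 23426 had 1 gene. Each gene was represented by its brightest such probe set, which gave 12614 genes. For some named genes the text also gives other probe sets. Suffixes s and x in a probe set's name mark probes that can read more than 1 transcript. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. All differences are log2 values of TDP-43 siRNA minus control siRNA, with the standard error of the fit. Figures were drawn with matplotlib 3.10.9.

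The text names Tardbp and Cacna1c, the 10 largest increases and the 10 largest decreases among genes past the threshold whose groups did not overlap (predicted genes and those with no symbol skipped), and up to 4 members with the smallest p of each list. The design, the naming rule, 23 gene lists and the alternatives were fixed before the data were examined, except where stated. The lists held 704 memberships. Of these, 638 had a probe set that names a single gene in the annotation used, and 562 were measured after the filter. Members without such a probe set may still be on the array. Lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists) and again with an estimated correlation. All 4 calls were lost with the latter. The estimate was 0.592 for glycolysis, 0.303 for cell cycle, 0.176 for heat shock and 0.0683 for RNA-binding and splicing factors. Each lay above the preset, so the preset p of these 4 lists may be too small. Members were adjusted over all genes and over the list alone. RNA quality was compared by exact permutation of the arrays. Probe sets of one gene were compared by fitting their difference with limma.

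The alternatives were other pseudocounts (1, and 42 as the 40th percentile), no filter or a 60% filter, quantile normalization, median centring, no intensity trend, robust variance, array weights, the mean of a gene's probe sets, single probe sets, other thresholds, plain two-sample tests, the replicate number as a block, fry in place of camera, other length limits and each array left out in turn. Leaving out both arrays numbered 3, and an estimated correlation with each array left out, were added after seeing the data.

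The steps were tested on simulated data with known answers. For the comparison of TDP-43 siRNA with control siRNA, over 12614 genes, 66% of the 100 genes changed by 0.5 and 81% of the 100 changed by 1 were recovered. Beside these, 17 unchanged genes were called, a larger share of the calls than the threshold of 0.05 allows for on average. For gene lists over 12614 genes, a shifted set of 20 genes gave a camera p of 4.62e-23, and 4% of 100 unshifted sets lay below 0.05. The simulated genes were drawn independently of one another. The 4% therefore says nothing about lists whose members move together, as those called here do. For probe set pairs, over 2000 pairs, 89% of 200 pairs changed by 1 were recovered and 10 unchanged pairs were called.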

Results

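Transcript levels were measured on 6 mouse expression arrays in MIN6, an insulin-producing cell line from a mouse beta cell tumour. On 3 arrays the cells had received a control siRNA and on 3 an siRNA against TDP-43, the RNA-binding protein encoded by Tardbp. Nothing in the labels says that the 3 replicates of a group were grown or treated on separate occasions. Each array gave a signal for 45101 probe sets, and the trimmed mean signal was 500.003 on every array. Median signals lay between 72.3 and 79.97, and the number of arrays limits the precision. Arrays correlated with one another between 0.985 and 0.992 across the log2 values of the 12614 genes left after the filter. The difference between 3' and 5' control probe sets, a sign of RNA quality, differed between groups by 0.02 for Gapdh (log2, exact permutation p = 0.4, two-sided) and by -0.03 for b-actin (exact permutation p = 0.2, two-sided). With 3 arrays against 3, the smallest exact p is 0.1.

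The first question was how far the siRNA lowered its target. Tardbp fell in all 3 TDP-43 siRNA arrays on all 5 of its probe sets. On its brightest probe set, 1423723_s_at, the control signals were 3748, 3940 and 3699, and those after TDP-43 siRNA were 2257, 2249 and 1836. The log2 difference was -0.85 (SE 0.08, n = 3 per group, limma adjusted p = 0.00175), with a 95% confidence interval from -1.04 to -0.66. The second bright probe set, 1455655_a_at, fell by 0.86. The 3 dimmer probe sets fell further, 1434419_s_at by 1.41, 1428467_at by 1.27 and 1436318_at by 1.24. The signal left was 40.4% on average over the dimmer probe sets and 55.3% over the brighter ones. The difference of -0.45 (SE 0.11) between their log2 changes had an exact permutation p = 0.1, two-sided. Taken singly, no dimmer probe set differed in its change from 1423723_s_at past the threshold. In the order above, the limma adjusted p was 0.162, 0.459 and 0.527 over 10812 pairs of probe sets. Without the intensity trend in the variance model, the adjusted p of Tardbp was 0.0587. The position the siRNA targets is not given in the sources used here, so each probe set checks only the part of the transcript it reads.

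**Figure D1:**
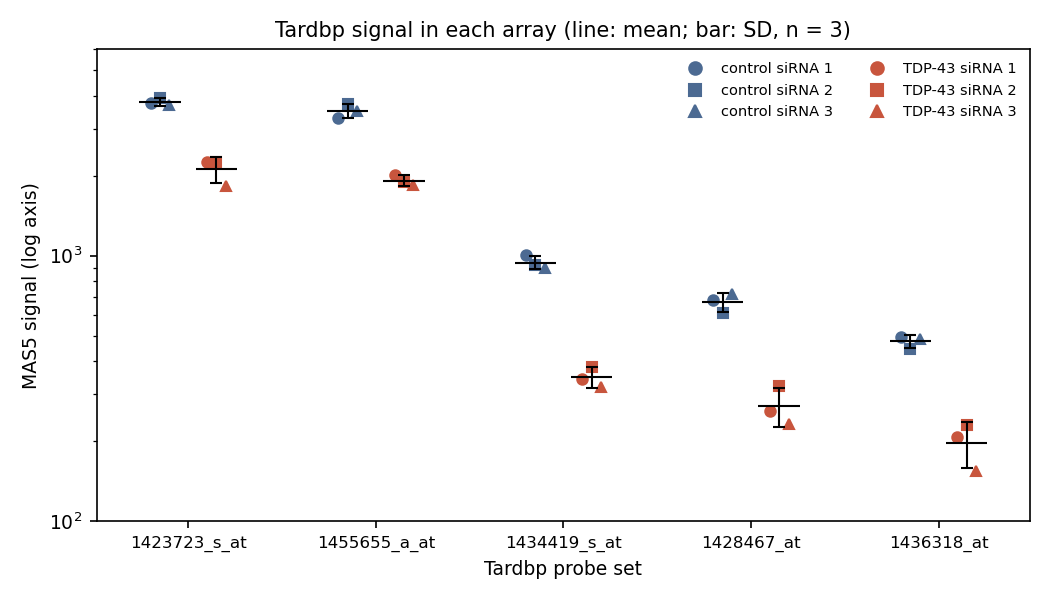
MAS5 signal of the 5 Tardbp probe sets on a log axis, one point per array, with the mean as a line and the SD as a bar (n = 3 per group). On 1423723_s_at the control arrays lie between 3699 and 3940 and the TDP-43 siRNA arrays between 1836 and 2257.

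The next question was which genes changed after TDP-43 siRNA. The design cannot tell an effect of lower TDP-43 from effects of the siRNA on other transcripts, which were not tested. Of 12614 genes tested, 94 changed, 21 higher and 73 lower after TDP-43 siRNA. Tecpr1, which takes part in autophagosome maturation, had the largest decrease (log2 difference -1.30, SE 0.14, limma adjusted p = 0.00225). Bccip, a partner of the DNA repair protein BRCA2, followed at -1.03 (SE 0.08, limma adjusted p = 0.00100). B3gat1, a glucuronosyltransferase of the HNK-1 carbohydrate epitope, had the largest increase among named genes (1.08, SE 0.15, limma adjusted p = 0.0113). Itgb8, an integrin beta subunit, rose by 1.07 (SE 0.18, limma adjusted p = 0.0249).

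Among the other large increases, Cth, the cystathionine gamma-lyase that makes cysteine, rose by 0.92. Gatm, the first enzyme of creatine synthesis, rose by 0.63. Slc7a3, a cationic amino acid transporter, rose by 0.55. Mxra8 rose by 0.57. Fam220a rose by 0.80, Cds2, a CDP-diacylglycerol synthase, by 0.69, Gabpb1, a subunit of the transcription factor GABP, by 0.66, and Styx by 0.50. Other probe sets changed less for several of these: the second probe set was at 0.14 for Fam220a and at -0.09 for Gabpb1, 1 probe set of Cds2 was at -0.07, and the next brightest of Styx was at 0.21. With the mean of a gene's probe sets, Cds2 (limma adjusted p = 0.0803), Gabpb1 (0.181), Styx (0.140) and Gatm (0.0632) no longer passed. With no filter on low values B3gat1, Itgb8, Cth, Gabpb1 and Gatm did not.

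Among the other large decreases, Mthfsd fell by 0.998, Dph6, which acts in diphthamide synthesis, by 0.99, and Wrnip1, a partner of the Werner helicase, by 0.96. Tapbp, the tapasin that loads peptides onto MHC class I, fell by 0.87, Thap12 by 0.86, Plp2 by 0.84 and Pcnx by 0.82. The second probe sets of Tecpr1, Tapbp and Thap12 were also lower, at -0.93, -0.73 and -0.91. The other 3 probe sets of Pcnx lay between -0.33 and -0.15, and with the mean of its probe sets Pcnx did not pass (limma adjusted p = 0.109). Cdh1, the epithelial cadherin, fell by 0.80 (SE 0.08, limma adjusted p = 0.00225), and its 3 TDP-43 siRNA arrays read 3027, 3021 and 2455 against control arrays from 4795 to 5078.

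All 94 genes had their 3 TDP-43 siRNA arrays on one side of all 3 control arrays. The threshold picks genes with a large difference against their spread, so this is no separate evidence for them. With the groups apart, leaving out or weighting arrays, or another pseudocount, cannot turn a gene's direction. Such a separation of the groups held for 18.3% of all genes, where chance gives 10%. Changes were mostly modest in size: the median absolute log2 difference of the changed genes was 0.61, and 3 were higher by 1 or more (B3gat1, Itgb8 and the predicted gene Gm11110 at 1.25, named after its value was seen and past the threshold in 1 of the 6 fits that left out 1 array) and 2 lower by 1 or more (Tecpr1 and Bccip). At an unadjusted p below 0.05 there were 1585 genes, where 630.7 would arise by chance. The count depended on single arrays: it was 32, 44 and 264 without control replicates 1, 2 and 3, and 48, 43 and 55 without TDP-43 siRNA replicates 1, 2 and 3. All 10 largest decreases passed in each of these 6 fits, but only 2 of the 10 largest increases did, Cds2 and Slc7a3. A variance model without the intensity trend gave 12 genes, among them none of the 10 largest increases, and plain two-sample tests with equal variances gave 0 after adjustment (1424 before).

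**Figure D2:**
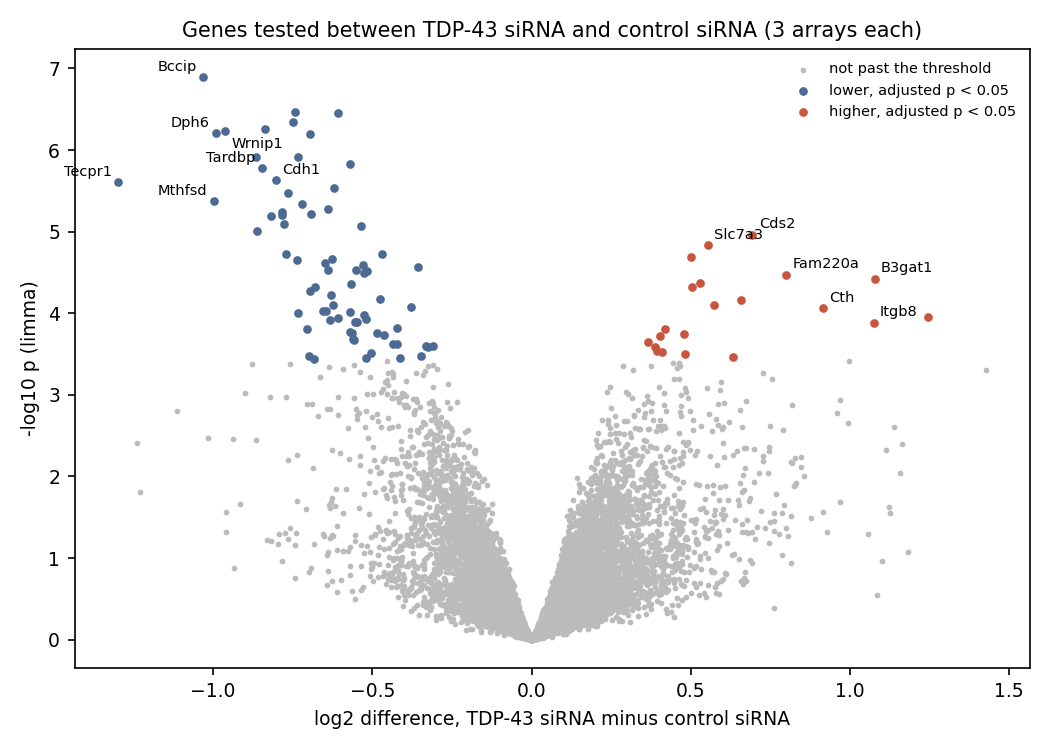
Log2 difference between TDP-43 siRNA and control siRNA on the horizontal axis against -log10 of the limma p on the vertical axis, one point per gene, with 21 higher and 73 lower genes in colour. Tecpr1 lies farthest to the left among the genes that passed, at -1.30.

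**Figure D3:**
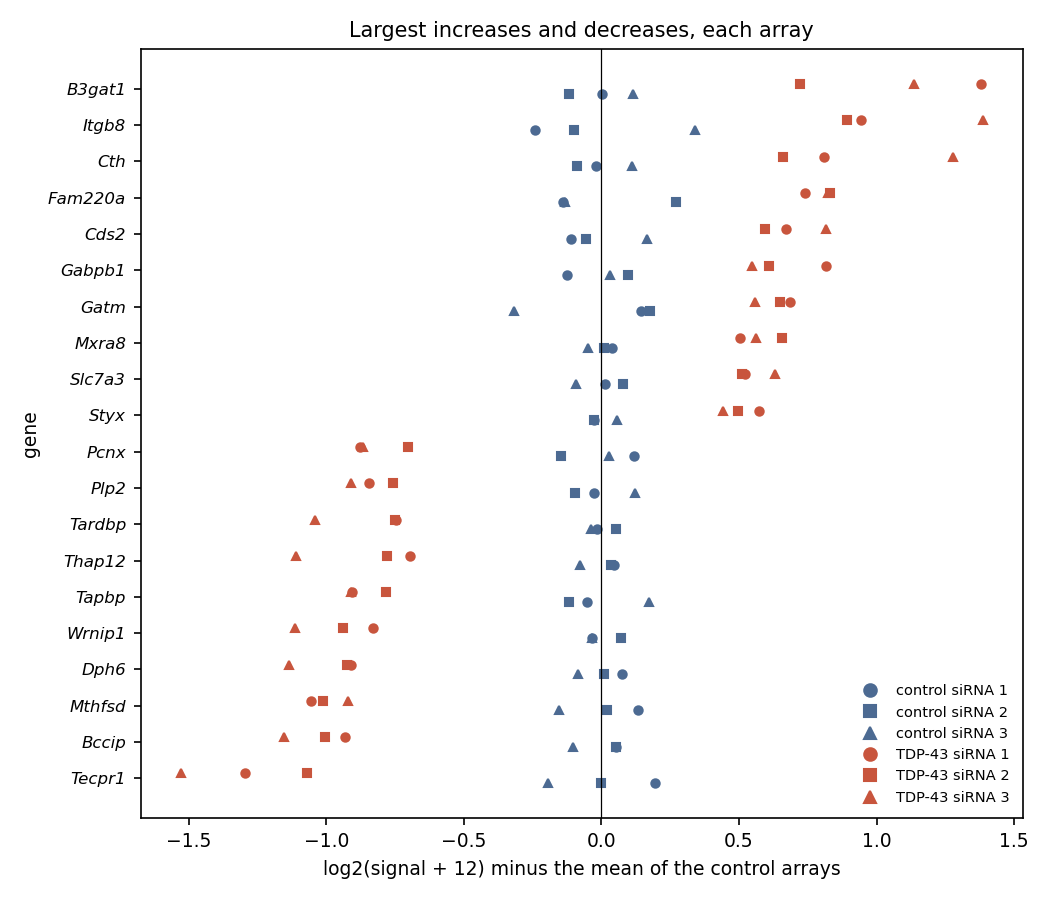
The 10 largest increases and 10 largest decreases, each array's log2(signal + 12) minus the mean of the 3 control arrays, one point per array. In every gene drawn the 3 TDP-43 siRNA arrays lie on one side of the 3 control arrays, as the naming rule requires.

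The published study of these cells centres on Cacna1c, the pore subunit of the CaV1.2 calcium channel, which these arrays helped to choose, so the gene is no independent evidence. Its brightest probe set, 1421297_a_at, differed by 0.05 (SE 0.11, limma adjusted p = 0.900), with signals of 341 in control and 355 in TDP-43 siRNA arrays. The 95% confidence interval ran from -0.20 to 0.31. The second probe set, 1435730_at, was at -0.26 (SE 0.12, limma adjusted p = 0.439 over probe sets), with an unadjusted 95% confidence interval from -0.52 to -0.00104 that leaves out 0. On it the 3 TDP-43 siRNA arrays, at 183, 203 and 199, lay below the control arrays at 230, 228 and 250. The sign for the gene turned to -0.11 with the mean of probe sets, to -0.03 without TDP-43 siRNA replicate 1 and to -0.01 without control replicate 3, none of which passed.

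Among voltage-gated calcium channel subunits, 0 of 11 measured members passed over all genes. Adjusted over the list alone, 1 was lower, Cacna2d1 at -0.45 (limma adjusted p = 0.00714 over the list). Cacna1d, the other L-type pore subunit of beta cells, was at 0.34, Cacna1h at -0.21 and Cacna1b at 0.31. The list did not shift as a whole (camera adjusted p = 0.744), and its median of 0.04 and mean of -0.01 differed in sign. Of 15 potassium and sodium channel genes 0 passed, nor did any adjusted over the list alone, with Kcnip1 at 0.32, Scn8a at 0.26, Scn3b at 0.33 and Kcnh2 at -0.12 (camera adjusted p = 0.483). Of the 45 exocytosis genes 0 passed by either adjustment. Sytl4, the granule protein granuphilin, was at 0.18, Exoc5 at 0.17, Cplx2 at 0.19 and Pclo at -0.51 (camera adjusted p = 0.339).

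Beta cell identity genes showed no shift that passed. Of 22 islet hormone and secretory granule genes 0 passed over all genes or adjusted over the list alone. Slc30a8, the granule zinc transporter, was at 0.25, Chgb at -0.21, Scg5 at 0.10 and Pcsk1n at 0.12 (camera adjusted p = 0.740). Ins2 was at -0.03 with a 95% confidence interval from -0.22 to 0.16, and Pdx1 at -0.02 with an interval from -0.23 to 0.19; these 2 genes were picked out after their values were seen. Of 17 beta cell transcription factors 0 passed over all genes, and 1 was higher adjusted over the list alone, Mnx1 at 0.42. Rfx3 was at -0.24, Pax6 at 0.18 and Bmi1 at 0.14 (camera adjusted p = 0.273). Of 24 genes of glucose sensing and metabolic coupling 0 passed by either adjustment, with Slc2a1 at 0.67, Atp2a3 at -0.37, Itpr3 at -0.26 and Atp2a2 at -0.10 (camera adjusted p = 0.950).

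Genes normally kept low in mature beta cells included 1 that rose, the tetraspanin Cd81 (0.41, SE 0.08, limma adjusted p = 0.0441), among 14 measured. Cd81 passed in only 1 of the 6 fits that left out 1 array, the one without control replicate 3. Adjusted over the list alone, 2 were higher and 1 lower. The lower one was Igfbp4 at -0.32, Slc16a1 was the second higher one at 0.32, and Ldha was at 0.79. The list did not shift as a whole (camera adjusted p = 0.261).

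Cell cycle and DNA replication genes were lower as a group. Of 43 measured, 2 fell over all genes, 0 rose and 41 did not pass. The mitotic kinesin Kif20a fell by 0.49 (SE 0.08, limma adjusted p = 0.0306) and the centromeric histone Cenpa by 0.33 (SE 0.06, limma adjusted p = 0.0389). Each passed in only 1 of the 6 fits that left out 1 array, for both the one without control replicate 3. Adjusted over the list alone, 15 were lower and 1 higher. Cdc20, the activator of the anaphase-promoting complex, was at -0.30. Cdkn1b, which by contrast restrains the cell cycle, was at -0.27. The median was -0.16, and 36 of 43 members lay below 0. The list shifted lower by camera with a preset correlation (adjusted p = 1.46e-10), and with adjusted p = 0.658 with an estimated correlation the call was lost. Each array's mean over the list lay between 0.00 and 0.12 in control arrays and between -0.16 and -0.01 after TDP-43 siRNA.

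Glycolysis genes were higher as a group, though not evenly across arrays. Of 18 measured, 0 passed over all genes. Adjusted over the list alone, 3 were higher and 1 lower. The higher ones were Eno2, a neuron-type enolase, at 0.39, and the monocarboxylate transporters Slc16a1 at 0.32 and Slc16a3 at 0.85; the lower one was Pfkfb2 at -0.26. The median was 0.34, and 17 of 18 members lay above 0. The list shifted higher by camera (adjusted p = 2.92e-05), a call lost with adjusted p = 0.658 with an estimated correlation. Control replicate 3 had a list mean of 0.21, close to the TDP-43 siRNA arrays at 0.18, 0.15 and 0.18, whereas control replicates 1 and 2 were at -0.38 and -0.34. For Ldha, control replicate 3 read 4780, TDP-43 siRNA arrays 4367, 4353 and 4547, and the other control arrays 1829 and 1884. Without control replicate 3, 12 members were higher (camera adjusted p = 9.13e-17, adjusted p = 0.0640 with an estimated correlation).

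Heat shock and stress granule genes were also higher as a group. Of 20 measured, 0 passed over all genes, and 3 were higher and 0 lower adjusted over the list alone. These were the chaperones Hspa1a at 0.97, Hspa1b at 0.82 and Hspa4 at 0.59, of which Hspa1a and Hspa1b are near-identical copies whose probe sets may share signal. Dnajb1 was at 0.19. The list was called by camera (adjusted p = 0.0138), a call lost with adjusted p = 0.658 with an estimated correlation. It was also lost without control replicate 2 (0.0899) or TDP-43 siRNA replicate 3 (0.157), with the mean of a gene's probe sets (0.0686) and without both arrays numbered 3 (0.0677). TDP-43 siRNA replicate 3 had the highest list mean, 0.27, against 0.02 and 0.03 in the other TDP-43 siRNA arrays.

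RNA-binding and splicing factor genes lay slightly lower as a group. Of 47 measured 0 passed by either adjustment, and 34 lay below 0, with a median of -0.05. Hnrnpa0 was at -0.31, Nova1 at -0.28, Hnrnpm at -0.14 and Khdrbs3 at 0.15. The list was called lower by camera (adjusted p = 0.0169), a call lost with adjusted p = 0.658 with an estimated correlation. It was also lost without control replicate 2 (0.110), TDP-43 siRNA replicate 1 (0.125) or TDP-43 siRNA replicate 3 (0.0861).

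**Figure D4:**
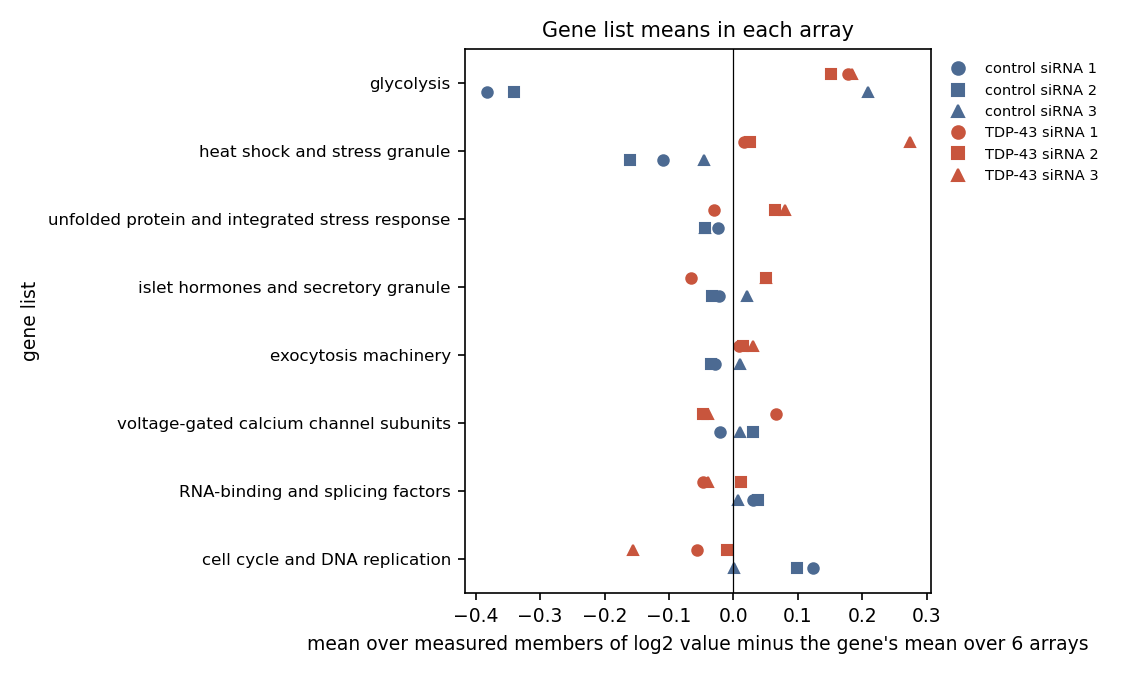
Mean over the measured members of 8 gene lists of the log2 value minus the gene's mean over the 6 arrays, one point per array. For glycolysis, control replicate 3 lies at 0.21 and the other control arrays at -0.38 and -0.34.

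Genes reported elsewhere as TDP-43 targets included 1 that fell among 28 measured, the Ran-binding Ranbp1 (-0.53, SE 0.06, limma adjusted p = 0.00431), and it was the 1 member past the threshold adjusted over the list alone. Tbc1d1 was at -0.43, Adnp2 at 0.20 and Nlgn1 at 0.47. The list did not shift (camera adjusted p = 0.950), and its median of 0.05 stood against a test pointing lower. Of 32 genes of axon, synapse and cell adhesion, 1 fell, Cdh1. Adjusted over the list alone, 1 was higher as well, Astn1 at 0.47, while Robo1 was at -0.76 and Cadm1 at 0.15 (camera adjusted p = 0.687). Of 26 p53 target and apoptosis genes, 1 fell, Zmat3, a zinc finger target of p53, by 0.62 (SE 0.10, limma adjusted p = 0.0194), also the 1 member that passed adjusted over the list alone. Zmat3 passed in 2 of the 6 fits that left out 1 array. Gadd45a was at -0.25, Ei24 at 0.13 and Ccng1 at 0.16 (camera adjusted p = 0.950), and the median of 0.02 again stood against a test pointing lower.

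Of 36 genes of the unfolded protein and integrated stress response 0 passed over all genes, and 1 was higher adjusted over the list alone, Phgdh of serine synthesis at 0.46. Psat1 was at 0.20, Atf4 at 0.25 and Chac1 at 0.29 (camera adjusted p = 0.191). Without TDP-43 siRNA replicate 1 the list was called higher (camera adjusted p = 0.00200), a call lost with adjusted p = 0.583 with an estimated correlation. Of 40 oxidative phosphorylation genes 0 passed by either adjustment, with Ndufv1 at -0.20, Sdhb at -0.15, Ndufa10 at -0.11 and Sdhd at -0.09 (camera adjusted p = 0.0798). That list was called lower without TDP-43 siRNA replicate 2 (0.0284) or control replicate 3 (0.0325), and both calls were lost, with adjusted p = 0.869 and adjusted p = 0.573 with an estimated correlation. Of 39 autophagy and lysosome genes 0 passed over all genes. Adjusted over the list alone, Ulk2, an autophagy kinase, was higher at 0.35 and Atg3 was lower at -0.44, with Atp6v1h at 0.19 and Rptor at -0.30 (camera adjusted p = 0.740).

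Of 22 cholesterol synthesis genes 0 passed by either adjustment, with Srebf1 at -0.26, Tm7sf2 at -0.25, Hmgcs1 at 0.24 and Pmvk at -0.41 (camera adjusted p = 0.483), and the median of 0.02 and mean of -0.03 differed in sign. Of 21 insulin signalling genes 0 passed over all genes. Eif4ebp1, a repressor of cap-dependent translation, was higher at 0.32 adjusted over the list alone, with Akt2 at 0.16, Shc1 at 0.17 and Pdpk1 at 0.11 (camera adjusted p = 0.273). Of 24 genes of the interferon and double-stranded RNA response 0 passed by either adjustment. Ifit3 was at 0.72, Stat2 at -0.37, Irf7 at -0.29 and Tap1 at 0.24 (camera adjusted p = 0.687).

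No marker of another cell type passed with all 6 arrays. Of 7 measured markers of alpha, delta, PP and epsilon cells 0 passed by either adjustment, with Gcg at -0.17, Ttr at -0.05, Rbp4 at 0.20 and Irx1 at 0.07 (camera adjusted p = 0.740). Without control replicate 3, Gcg was at -0.32 and passed (limma adjusted p = 0.0480). MIN6 cells gave strong signals for Gcg (9264 in control arrays) and Ttr (22767) themselves. Of 5 acinar and duct cell markers 0 passed by either adjustment, with Car2 at -0.76, Krt7 at -0.10, Cela3b at 0.27 and Cela1 at 0.15 (camera adjusted p = 0.687). Of 6 markers of fibroblasts, endothelial and immune cells 0 passed by either adjustment, with Col1a2 at -0.63, Fn1 at -0.51, Thy1 at 0.29 and Lyz2 at 0.26 (camera adjusted p = 0.687), and the median of 0.03 and mean of -0.09 differed in sign. For Car2 and Col1a2 all 3 TDP-43 siRNA arrays lay below the 3 control arrays. The size for Car2 hung on single arrays, at -0.31 without TDP-43 siRNA replicate 3 and -1.08 without TDP-43 siRNA replicate 2.

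Loss of TDP-43 in mouse brain is known to lower transcripts of genes with long introns, which made gene length the last comparison. Genes that span 100 kb or more had a median log2 difference of 0.03 (1667 genes) against 0.01 for the others (10887 genes). They did not differ by camera, nor did genes above limits of 50 kb or 200 kb (adjusted p = 0.455 for each, adjusted over the 3 limits). Among the long genes, 5 were higher and 8 lower.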

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

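The tests of background signal for Tardbp, of control replicate 3 and of the glycolysis list from well to well were chosen only after the result was seen, as was the list of hypoxia-response genes.

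Probe sets with no single named gene, which no comparison above used, also changed: of 3596 tested, 5 were higher and 10 lower after TDP-43 siRNA. Probe set 1418072_at fell from a mean signal of 6389 to 3872, and 1438412_at rose from 586 to 1031.

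More genes were lower (73) than higher (21) after TDP-43 siRNA. The scaling of the arrays is argued against, since 74.4% of the called genes were still lower under median centring, the smaller share of both scaling alternatives. Without control replicate 3, 43.6% of 264 called genes were lower (78.2% to 89.6% with each of the other arrays left out), because higher genes went from 21 to 149 while lower ones also went up, from 73 to 115. That array may hide increases, or control replicates 1 and 2 may lie low in those genes, which these arrays cannot tell apart. Control replicate 3 correlated with these at 0.989 and 0.988, and they with each other at 0.990. Removal of control replicate 3 does not account for the decreases. No biological explanation was tested, nor were effects of the siRNA on transcripts other than its target.

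The dimmer Tardbp probe sets fell more than the brighter ones on average, though none taken singly differed from the brightest past the threshold. Background signal would compress the change of dim probe sets, the opposite of the difference seen, -0.45 (SE 0.11), which is the pattern itself and not a separate test. Saturation at the top of the signal scale is argued against. The brighter probe sets averaged 3796 and 3506 in control arrays, and the highest signal of each array lay between 23787 and 26055. Saturation of these probe sets alone could not be told apart. Among probe sets at least as bright, 3 had a larger change at an unadjusted p below 0.05, 2 of Dynlt3 and 1 of Hspa1b. Besides these, 1 of Egr1 had a larger change (1.09) without that p. The Egr1 value hung on single arrays, at 0.28 without control replicate 3 and 2.35 without TDP-43 siRNA replicate 3. Signal from other transcripts also stays open. A constant 24.8% of the control signal in the brighter probe sets would be enough. Any smaller fall of the brighter probe sets gives a possible share, so this value is no test. A change in the balance of Tardbp transcript forms, a biological candidate explanation, was not tested.

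Glycolysis genes were higher and cell cycle genes lower as groups by camera with a preset correlation, and both calls were lost with adjusted p = 0.658 with an estimated correlation. A state of the cultures that varies from well to well may account for the glycolysis shift, since the largest range within a group was 1.73 times the difference between groups. For cell cycle genes the same ratio was 0.981, between the bounds set for either answer. A hypoxia-type response may run through the glycolysis shift: over the 6 arrays, the mean of 20 measured hypoxia-response genes outside the glycolysis list followed it (Spearman rho 0.886, exact permutation p = 0.0333; Pearson r 0.983, exact permutation p = 0.00833), but r was 0.642 without control replicates 1 and 2, on which the relation rests. That list was not called with an estimated correlation (p = 0.206), and an effect of lower TDP-43 itself stays open beside both.

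Other splits of the 6 arrays cannot give a share under 0.05, as there are 10. The real split gave 94 changed genes and the highest other split 0, so 1 of the 10 splits gave as many. For called lists, 5 of the 10 splits gave at least 4, the highest other split 5. For long genes, 7 of the 10 splits gave as small a p as the real 0.455, the lowest other p being 0.0110. For genes whose probe sets responded differently, 2 of the 10 splits gave at least the real 1, the highest other split 5.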

How the results depend on the processing

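Leaving out both arrays numbered 3, and an estimated correlation with each array left out, were chosen only after the result was seen; the other alternatives were planned. All 94 genes kept their direction in each fit with 1 value per gene. Only scaling or the mean of probe sets could have changed it. The counts moved. Genes changed numbered 51 with no filter on low values (8 higher, 43 lower), 12 with no intensity trend (1 higher, 11 lower), 163 with array weights (56 higher), 165 for single probe sets (37 higher, 128 lower), 214 at an adjusted p below 0.1 (68 higher, 146 lower), 39 below 0.01 (3 higher, 36 lower), 226 without both arrays numbered 3 (125 higher) and 0 with plain two-sample tests (0 higher, 0 lower; 1424 genes at an unadjusted p below 0.05). With the mean of probe sets 12 genes were higher. That choice ended the calls of Cds2 (0.44, limma adjusted p = 0.0803), Gabpb1 (0.29, 0.181), Styx (0.30, 0.140), Gatm (0.63, 0.0632), Pcnx (-0.41, 0.109), Cenpa (-0.33, 0.121) and Cd81 (0.41, 0.0564). No filter on low values ended those of B3gat1 (0.0526), Itgb8 (0.0989), Cth (0.0690), Gabpb1 (0.0512), Gatm (0.140), Kif20a and Cenpa (0.0660 each), Cd81 (0.110) and Zmat3 (0.0526). Quantile normalization ended that of Gatm (0.0596), median centring those of Kif20a and Cd81 (0.0759 each) and Cenpa (0.133), and leaving out both arrays numbered 3 that of Zmat3 (0.0593). No intensity trend ended the calls of all 10 largest increases, of Tecpr1, Tapbp, Thap12, Tardbp and Pcnx among the decreases, and of Cdh1, Ranbp1, Kif20a, Cenpa, Cd81 and Zmat3. With each array left out in turn, the count ran from 32 without control replicate 1 to 264 without control replicate 3, with 5 to 149 higher and 27 to 115 lower. Array weights were lowest for control replicate 3 (0.614). Without the intensity trend the limma adjusted p of Tardbp was 0.0587 at the same difference, -0.85, and the cause was not tested.

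Pairing by replicate number could not be told from 3 arrays per group. Deviations of arrays with the same number correlated at -0.12, -0.14 and 0.24, the best match only for number 3. With the number as a replicate block 127 genes changed, 41 of them higher, and 85 were shared with the 94.

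The 4 list calls were lost with an estimated correlation (adjusted p = 0.658 each) and with the replicate block and an estimated correlation (0.888 each). None of the 4 passed with fry, which tests a list against no change, not against the other genes. Its adjusted p was 0.318 for RNA-binding and splicing factors, 0.291 for cell cycle, 0.351 for glycolysis and 0.318 for heat shock. With fry and the replicate block these were 0.337, 0.182, 0.436 and 0.406. The heat shock list was also lost with the mean of probe sets (0.0686) and without both arrays numbered 3 (0.0677). With each array left out, the camera adjusted p ran from 0.00204 to 0.125 for RNA-binding and splicing factors, from 0.000124 to 0.157 for heat shock, from 4.32e-13 to 2.79e-06 for cell cycle and from 9.13e-17 to 0.00374 for glycolysis. With an estimated correlation as well, it ran from 0.499 to 0.957 for RNA-binding and splicing factors, from 0.573 to 0.957 for heat shock and for cell cycle and from 0.0640 to 0.957 for glycolysis. The fry values above test for a shift in 1 direction, which 0 of 23 lists passed. For change in either direction, fry passed 8 of 23 lists: calcium channel subunits, reported TDP-43 targets and cholesterol synthesis (adjusted p = 0.00863 each), genes kept low in mature beta cells (0.0117), beta cell transcription factors (0.0215), cell cycle (0.0244), RNA-binding and splicing factors (0.0363) and potassium and sodium channels (0.0445). Of the genes picked by the naming rule that did not pass, 16 passed with 1 array left out. Without control replicate 3 these were Ldha (1.25), Slc16a3 (1.21), Hspa1b (1.06), Slc2a1 (0.94), Eno2 (0.50), Ulk2 (0.40), Eif4ebp1 (0.35), Slc30a8 (0.29), Gcg (-0.32), Gadd45a (-0.35), Cdc20 (-0.35) and Pmvk (-0.57), and of genes named outside that rule Pdk1, P4ha1, Ak4 and Ddit4 also passed there. Without TDP-43 siRNA replicate 2 they were Hspa1a (1.20) and Hspa4 (0.72), without control replicate 2 Cacna2d1 (-0.55) and without TDP-43 siRNA replicate 1 Robo1 (-1.05). The block also brought Cdc20, Atg3, Hspa1a, Hspa1b and Atp2a3 past the threshold, and P4ha1 (limma adjusted p = 0.0337) among genes named outside the rule. It changed no other call of a gene named in the text. Dim genes are limited by signal over background, and no detection calls were used here.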

Other observations

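The test of probe sets within a gene was chosen only after the data were examined.

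Without control replicate 3, 264 genes changed, 149 of them higher. Ldha, the lactate dehydrogenase of glycolysis, was at 1.25, the glucose transporter Slc2a1 at 0.94, Pdk1, which restrains pyruvate use in mitochondria, at 0.89, the prolyl hydroxylase subunit P4ha1 at 1.08, Ak4 at 1.30 and Ddit4 at 0.83, each past a limma adjusted p of 0.05. Ldha and Slc2a1 are named by the naming rule, and Pdk1, P4ha1, Ak4 and Ddit4 were named after their values were seen. In the main fit with all 6 arrays none of these genes passed. P4ha1 did pass with the replicate block (limma adjusted p = 0.0337) and with array weights (limma adjusted p = 0.0358).

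Fbxo3, a ubiquitin ligase subunit, was the 1 gene of 6192 whose probe sets changed by different amounts past the threshold. Its probe set 1423490_at was at 0.03 and 1455047_at at -1.18, a difference of 1.21 (SE 0.11, limma adjusted p = 0.00808 over 10812 pairs). Of the other Fbxo3 probe sets, 1431078_at was at -0.89, and 1441019_at and 1423491_at were at -0.14 each, none past the threshold against 1423490_at. At an unadjusted p below 0.05 there were 696 pairs, where 540.6 would arise by chance.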
